A study of Mus musculus with 65 samples.

How the data were processed

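Single cells were taken from the developing cortex of C57BL/6J mouse embryos at E13.5, when neural progenitors of the cortical wall divide and give rise to neurons. Per the labels' protocols, cortical hemispheres were dissected, the ganglionic eminences were removed, the brains of all embryos were pooled, and cells that excluded propidium iodide were sorted singly into the lysis buffer of a SMARTer full-length cDNA kit. Libraries were sequenced on an Illumina instrument. The kit gives reads along whole transcripts without molecular identifiers, so that a read is not an independent molecule, and strand is not kept.

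The deposited table holds raw counts, that is, whole-number read counts per gene and cell for 11971 genes and 65 cells. TopHat2, HTSeq and the mouse build mm9 are named per the submitters' processing notes, which give no versions or roles. The gene annotation used for counting is not given in the sources used here. Every deposited gene had reads in at least 5 cells. Genes are named by the symbols of the table. Reads of near-identical paralogs, such as the tubulin, actin and globin genes, and of antisense transcripts that overlap another gene, such as Dlx6as1 with Dlx6, cannot be told apart with certainty.

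The 65 cells form 1 group, because the labels give every cell the same strain, age and tissue. Their titles part them into 3 numbered sets of 31, 13 and 21 cells that the labels do not explain. These title sets were treated as possible batches and never as conditions, and score correlations and the main shares of cells are also given within them. Because the embryos were pooled and no animal is named, the cells are not replicates of animals. No p-value, standard error or test was therefore made from cells, and correlations and variances describe these cells only. No 2 cells held identical values, and the correlation of log2(CPM+1) between cells ranged from 0.237 to 0.519.

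Counts were scaled by each cell's total to CPM, and logged as log2(CPM + 1). Cells needed at least 1000 genes with a read and genes needed a read in at least 5 kept cells, and neither filter removed anything. A gene was counted as expressed in a cell at 10 CPM or more. Variable genes were ranked, among genes of mean CPM 5 or more, by the excess of the log10 squared coefficient of variation over a lowess trend on log10 mean, with each gene's highest cell set to the value of the next. Genes were called variable in every set when they ranked among the 500 highest over all cells and within each of the 3 title sets.

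Before the data were examined, 25 gene lists with 405 entries were written down, of which 366 were measured, 3 of them under an older symbol paired with the current one in a RefSeq gene table. Each list with 5 or more measured genes was described by the share of its genes' variance on their first principal component. That share was ranked among 10000 random lists of the same size drawn from 20 bins of matched mean expression. A list score was the mean log2(CPM + 1) of the measured genes minus that of up to 100 control genes per gene from the same bin. Score correlations were set beside the range holding the central 99% of correlations between random lists of matched expression. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

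Cells were clustered by Ward linkage on 5 principal components of the 1000 most variable genes without the G1/S and G2/M lists, and the number of clusters between 2 and 6 with the highest mean silhouette was kept. A cluster was named only from the fixed markers. No doublet caller was run on 65 singly sorted cells. The presence of Xist and Y-linked transcripts in the same cell was counted instead. Genes were named by a rule fixed together with the lists. It took up to 8 members of each list with the highest variability or loading and up to 25 genes variable in every title set. It added the 15 genes outside the lists at each end of the neuronal minus progenitor axis, among genes of mean CPM 10 or more with the same sign in every title set, and 21 fixed genes. Gad1, 1 of those 21, is not analysed here. Genes outside the rule are named only where stated.

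On counts simulated from the real gene means, spreads and totals over 11866 genes, with 20 cells changed in lists of 20 genes, 3 of 3 lists planted at 8-fold, 2 of 3 at 4-fold and 0 of 3 at 2-fold passed the 99th percentile, as did 1.5% of 200 lists of unchanged genes. Unchanged genes were simulated as independent, so that this 1.5% does not show how often real lists pass through shared batch or cell type differences. Simulated with a fixed spread over 9613 ranked genes, the 500 highest held 28.4%, 98.5% and 100% of the genes planted at 2-fold, 4-fold and 8-fold. There every gene had the same spread, unlike the real genes, and all cells were ranked together. These shares therefore do not bear on the count of genes variable in every title set. The list analysis can therefore miss programmes that change by 2-fold in part of the cells.

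Alternatives covered the cell and gene filters, scran size factors, thinning of every cell to 85338 reads, the pseudocount, the expression level, control genes, centring within title sets, a correction for detected genes, leaving out each title set, and the choices behind the rankings and clusters. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and statsmodels 0.14.6, and R 4.3.3 with scran 1.30.0. Transcript lengths for a check in the closing section came from GENCODE vM21, a later build than mm9, matched by symbol, and no coordinates are given.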

Results

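The transcriptomes of 65 single cells from the cortex of pooled E13.5 mouse embryos were examined for variation between cells. The series design names this transcriptional heterogeneity as its subject, and its title names gene set overdispersion as the approach. All 65 cells belong to 1 group, cortical cells labelled as neural progenitors, with 31, 13 and 21 cells in title sets 1, 2 and 3. There are no replicate animals, so that errors below are spreads across cells or counting intervals.

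Cells had a median of 14609426 reads in genes, from 85338 to 32130629. The median total was 14032041 in set 1, 8127759 in set 2 and 22483962 in set 3, and 3 cells had fewer than 1000000 reads. A median of 6276 genes had a read in a cell, from 2403 to 7337, and a median of 2768 genes reached 10 CPM. Thinned to 85338 reads, the median number of detected genes was 2965. Values of 1 to 3 reads made up 27.6% of all gene and cell pairs with reads but held 0.0158% of the reads. For example, Gad2, which encodes a GABA-synthesising enzyme, had at least 1 read in 63 cells and reached 10 CPM in 11, so that 10 CPM was used in place of 1 read. In the shallowest cell, of set 2, and in every cell thinned to its 85338 reads, 1 read already reached that level. All 2403 genes detected in the shallowest cell therefore counted as expressed.

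Several genes of young neurons were among the most variable in every title set. Of 9666 ranked genes, 26 were among the 500 most variable within each of the 3 sets, where 1.34 would be if the sets' rankings were independent. Of these, 23 were also among the 500 most variable over all cells. They included the neuronal microtubule genes Stmn2 (mean 906 CPM, SD across cells 1485), Map1b (2845, SD 3547), Tuba1a (2703, SD 3016) and Dcx (675, SD 1081). Stmn3, Rtn1, Tagln3, Dpysl3, Enc1 and Myt1l, all expressed in young neurons, and the neuronal transcription factor Sox11 were also in this group. Top2a, a topoisomerase of dividing cells and the only member of the cell cycle lists (249 CPM, SD 465), and the histone variant gene H2afz (4709 CPM, SD 3841) were among them. So were the regional transcription factors Sp8 (303 CPM, SD 736) and Nr2f2 (267 CPM, SD 859), and Dlx5 (117 CPM, SD 323), a homeobox gene of ventral forebrain and interneurons. The others were the nuclear noncoding RNA Malat1, Nfib, the cytoskeletal genes Actb, Actg1 and Tmsb4x, and Ndn and Mest, both imprinted genes. Between pairs of title sets, 61, 69 and 52 of the 500 most variable genes were shared, against 25.9 for independent rankings.

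No test stands behind this count, which depends on the ranking. It was 12 when no cell was set to the next value (7 of the 23 genes kept), 15 with scran size factors (12 kept) and 36 when the 1000 highest were compared, and 11 were kept with the 3 highest cells replaced. The number for independent rankings is a reference only, because all sets were ranked by the same method with the same mean filter. Overlap beyond it can come from the method as well as from the cells, and these were not told apart.

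Programmes of mitosis, DNA replication, neuronal maturation and progenitor identity varied as coordinated groups of genes. The first component held 45.7% of the variance of the 36 G2/M genes (random lists 9.48%), 40.5% for the 27 G1/S genes (10.7%), 39.6% for the 22 neuronal maturation genes (11.5%) and 27.2% for the 20 apical progenitor genes (12.2%). It held 35.4% for the 13 measured intermediate progenitor genes (14.9%) and 43.8% for the 12 interneuron and ventral telencephalon genes (15.1%). Synapse and ion channel genes (25.4%, random lists 9.95%), axon guidance and adhesion genes (19.3%, 11.1%), ribosomal protein genes (39.2%, 16.7%) and glycolysis and hypoxia genes (21.1%, 14.01%) also passed. Of the 21 lists with 5 or more measured genes, 16 lay above the 99th percentile of random lists of matched expression.

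Lists of 2 developmental signalling pathways also passed. The Notch list, with receptors such as Notch1 and targets such as Hes1 and Nrarp, had 21.7% on its first component (random lists 13.4%). The Wnt list, with Axin2, Sfrp1 and Tcf7l2, had 16.7% (random lists 12.3%). Both, like the glycolysis and hypoxia list, passed within set 1 only. In set 3 the Notch, Wnt and glycolysis lists lay at percentiles 54.3, 43.9 and 82.8, and without set 1 at 97.8, 93.8 and 80.3. Cortical area patterning genes lay at percentile 96.8 and chromatin regulator genes at 94.9. Oxidative phosphorylation genes lay at 60.4, housekeeping genes at 52.3 and immediate early and heat shock genes, 5 of 14 measured, at 35.5.

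Some lists of other cell types passed as well. The mural and meningeal list had 81.5% of its variance on the first component (random lists 23.7%) and the Cajal-Retzius list 33.5% (random lists 19.7%). Without the 2 cells farthest out on that component, an alternative chosen after seeing the data, they fell to percentiles 57.1 and 94.7, although the Cajal-Retzius list lay at 100, 99.7 and 97.2 within sets 1, 2 and 3. The erythroid list had 49.5% (random lists 27.6%) and fell to percentile 25.3 when genes were centred within title sets, while it lay at 100 within set 2 and at 12.4 within set 3. The microglia list had 66.6% (random lists 23.6%), although C1qb, a complement gene of microglia, averaged 0.0489 CPM and never reached 10 CPM. Endothelium and oligodendrocyte precursor lists had 2 and 3 measured genes and were not ranked, nor were Xist and the 4 Y-linked genes. In every title set, 6 lists passed: apical progenitor, neuronal maturation, interneuron and ventral telencephalon, G1/S, G2/M, and synapse and ion channel.

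**Figure D1:**
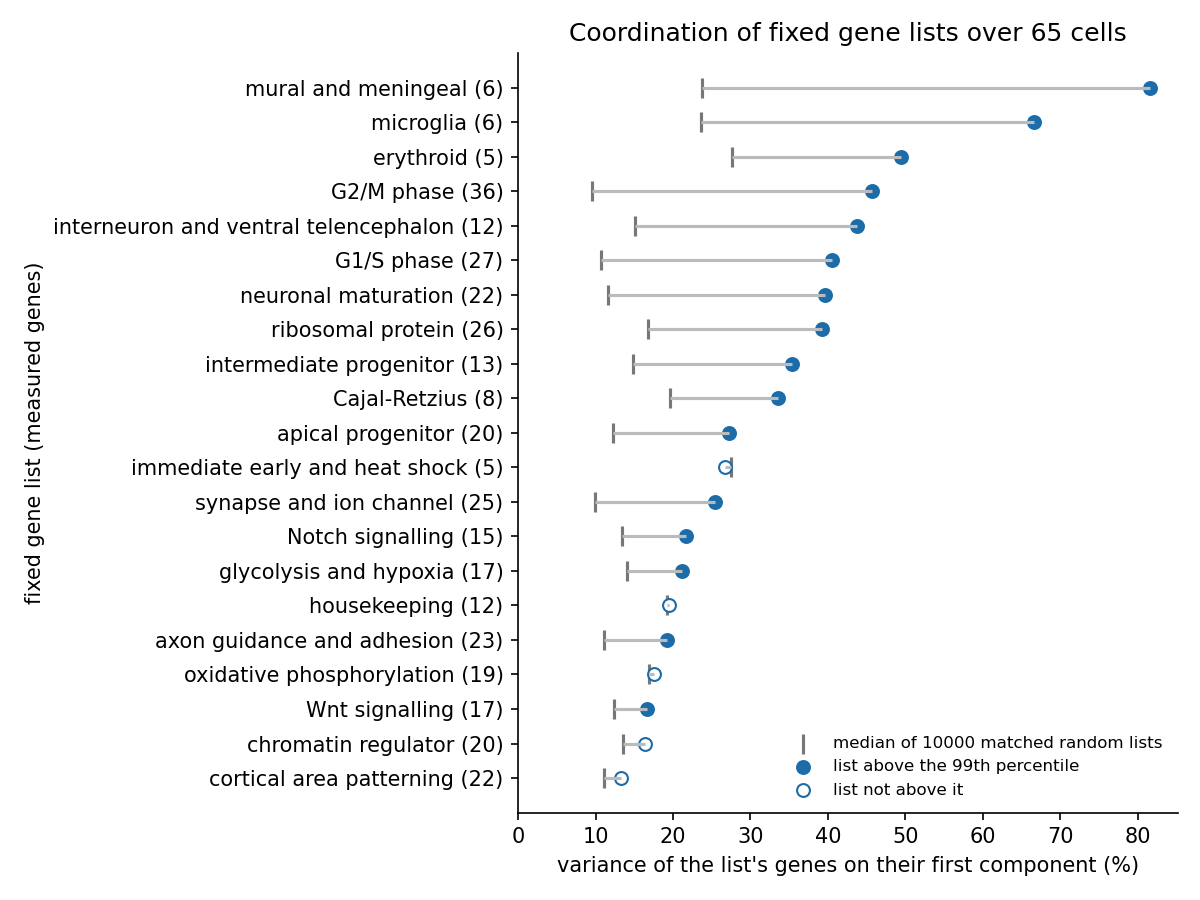
Percent of variance of each fixed list's genes on their first principal component over 65 cells (points) against the median of 10000 random lists of matched expression (ticks), with the number of measured genes in brackets. Filled points mark the 16 of 21 lists above the 99th percentile, such as G2/M at 45.7%, and open points the other lists, such as housekeeping at 19.4%.

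The question of whether these cells spread along a differentiation axis was addressed with the apical progenitor and neuronal maturation scores. Cells with high levels of radial glia genes had low levels of neuronal genes. Sox2, a transcription factor of neural progenitors, reached 10 CPM in 22 cells, and Neurod6, a transcription factor of cortical excitatory neurons, in 16. No cell had both, where 5.42 would if the genes were independent (0 of 65 cells, exact upper limit 5.52%). Pax6, which specifies cortical progenitors, was at that level in 29 cells, Hes1, a Notch target, in 21 and its relative Hes5 in 3. Tubb3, a neuronal tubulin, was at that level in 53 cells, Dcx in 34, and Tbr1, a transcription factor of early-born cortical neurons, in 19, 14 of them with Neurod6 (4.68 if independent).

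The 2 scores were inversely related across cells, which are not independent replicates (Pearson r = -0.787, Spearman rho = -0.815, n = 65). Correlations between random lists of matched expression ranged from -0.336 to 0.349. Within title sets 1, 2 and 3, r was -0.784, -0.935 and -0.732, and without the 2 cells farthest from the median progenitor score it was -0.803. The apical progenitor score was nearly unrelated to the number of detected genes (r = 0.109), and the neuronal score weakly so (r = -0.244).

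Genes outside the lists were then ordered along the neuronal minus progenitor score. Toward the neuronal end lay the actin-binding genes Tmsb10 (rho = 0.734) and Tagln3 (0.729), the growth cone protein gene Dpysl3 (0.729), the cannabinoid receptor gene Cnr1 (0.706), Nrep (0.695) and the neuronal RNA-binding protein gene Elavl3 (0.688). Cnr1 reached 10 CPM in 22 cells, with a median of 1083 CPM there. Toward the progenitor end lay Hn1l (rho = -0.701), the peroxidase gene Prdx1 (-0.670), the secreted glycoprotein gene Fstl1 (-0.663), the RNA decay factor Zfp36l1 (-0.652), fibronectin (Fn1, -0.633) and the hedgehog co-receptor Gas1 (-0.612). Psat1, an enzyme of serine synthesis, had a rho of -0.636, and Phgdh, the first enzyme of that pathway and a member of the progenitor list, -0.662. The tubulin genes Tuba1a (0.728) and Tuba1b (-0.603) lay at opposite ends. These genes were picked by rho among 8377 genes of mean CPM 10 or more. Of the 3297 outside the lists with 1 sign in every title set, 1152 were positive and 2145 negative.

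Several other fixed lists fell mostly to 1 side of the axis, where 59.7% of all 8377 genes, and 8 of 12 housekeeping genes, had a negative rho. Of 25 synapse and ion channel genes, 24 had a positive rho, 18 of them in every title set, including the sodium channel gene Scn3a (0.603), the calcium channel subunit gene Cacna2d1 (0.576) and Snap25, a vesicle fusion protein gene (0.651, and also in the neuronal list). Of 23 axon guidance and adhesion genes, 19 were positive, 11 of them in every title set, such as the semaphorin receptor gene Plxna4 (0.644) and the adhesion genes L1cam (0.494) and Cntn2 (0.481). All 26 ribosomal protein genes were negative, such as Rps18 (-0.440) and Rpl32 (-0.386), 21 of them in every title set. Of 17 glycolysis and hypoxia genes, 14 were negative, 6 of them in every title set, including the hexokinase gene Hk2 (-0.475) and the lactate dehydrogenase gene Ldha (-0.451, but 0.0649 within set 3). Of 17 Wnt genes, 15 were negative, 7 of them in every title set, such as Sfrp1 (-0.513), Tcf7l2 (-0.487) and Axin2 (-0.443), while the ligand gene Wnt7b was positive (0.536). Of 15 Notch genes, 11 were negative, but Notch1, Notch2, Hes1 and Hes5 are also in the progenitor list, and of the other 11 genes 7 were negative, close to the share among all genes. The 20 progenitor genes and 21 of the 22 neuronal genes took the sign of their own list, which the axis sets in part.

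Cells with Eomes often carried other genes of the intermediate progenitor list. Eomes, the transcription factor that marks intermediate progenitors, reached 10 CPM in 20 cells. Of these, 14 also had the proneural gene Neurog2 (5.85 if independent), 13 had Neurod1 (5.54) and 10 had Neurod6 (4.92), whereas 6 had Pax6 (8.92) and 3 had Sox2 (6.77). Neurog2 and Neurod1 belong to the same list as Eomes, and of the 10 cells with Neurod6, a gene of neurons, 8 were in set 1 and 1 each in sets 2 and 3. Along the axis, Neurod1 had a rho of 0.497, Eomes 0.297, Neurog2 -0.0759 and the antiproliferative gene Btg2 -0.325. Over the list, 11 of 13 genes had a positive rho, 5 of them in every title set.

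The intermediate progenitor and neuronal scores were not related beyond random lists (r = 0.126, rho = 0.263, n = 65 cells, random range -0.322 to 0.340). Within title sets r was 0.176, -0.162 and 0.129, and without the 2 cells farthest from the median intermediate progenitor score it was 0.144.

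Mitotic genes were found mostly in cells with low neuronal scores. Of the 36 G2/M genes, all had a negative rho with the neuronal minus progenitor axis, 33 of them in every title set, including the cyclin gene Ccnb1 (-0.552), Top2a (-0.544), the mitotic kinesin gene Kif23 (-0.517) and the proliferation marker Mki67 (-0.412). Ccnb1 reached 10 CPM in 26 cells, Mki67 in 25 and Top2a in 32. Top2a was at that level in 17 of the 22 cells with Sox2 (10.8 if independent) and in 5 of the 16 cells with Neurod6 (7.88 if independent). Cells with 18 or more of the 36 G2/M genes numbered 15 of 65 (23.1%, 95% interval 13.5 to 35.2), and 8 cells lay within 3 genes of that bound. The share differed by title set, with 10 of 31, 1 of 13 and 4 of 21 cells in sets 1, 2 and 3.

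The G2/M and neuronal scores were inversely related (r = -0.585, rho = -0.647, n = 65 cells, random range -0.341 to 0.337). Within title sets r was -0.561, -0.633 and -0.615, and without the 2 cells farthest from the median G2/M score it was -0.609.

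Replication genes were carried partly by the same cells as mitotic genes and partly by others. All 27 G1/S genes had a negative rho with the axis, 26 of them in every title set, including the chromatin remodeller gene Hells (-0.712), the replicative helicase gene Mcm3 (-0.654), the ribonucleotide reductase gene Rrm2 (-0.585) and the sliding clamp gene Pcna (-0.493). Cells with 14 or more of the 27 G1/S genes numbered 22 (33.8%, 95% interval 22.6 to 46.6), with 15 cells within 3 genes of that bound, and made up 14 of 31, 4 of 13 and 4 of 21 cells in sets 1, 2 and 3. Of these 22, 11 also had 18 or more G2/M genes. The shallowest cell, of set 2, was among the 22 with 14 G1/S genes, and at its depth single reads pass 10 CPM.

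The G1/S and G2/M scores were positively related (r = 0.386, rho = 0.634, n = 65 cells, random range -0.332 to 0.341). Within title sets r was 0.415, 0.429 and 0.324. The last lay inside the random range of all 65 cells, but no random range was computed for the fewer cells of a set. Without the 2 cells farthest from the median G1/S score r was 0.442. The strength of this relation depended on the kind of correlation.

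**Figure D2:**
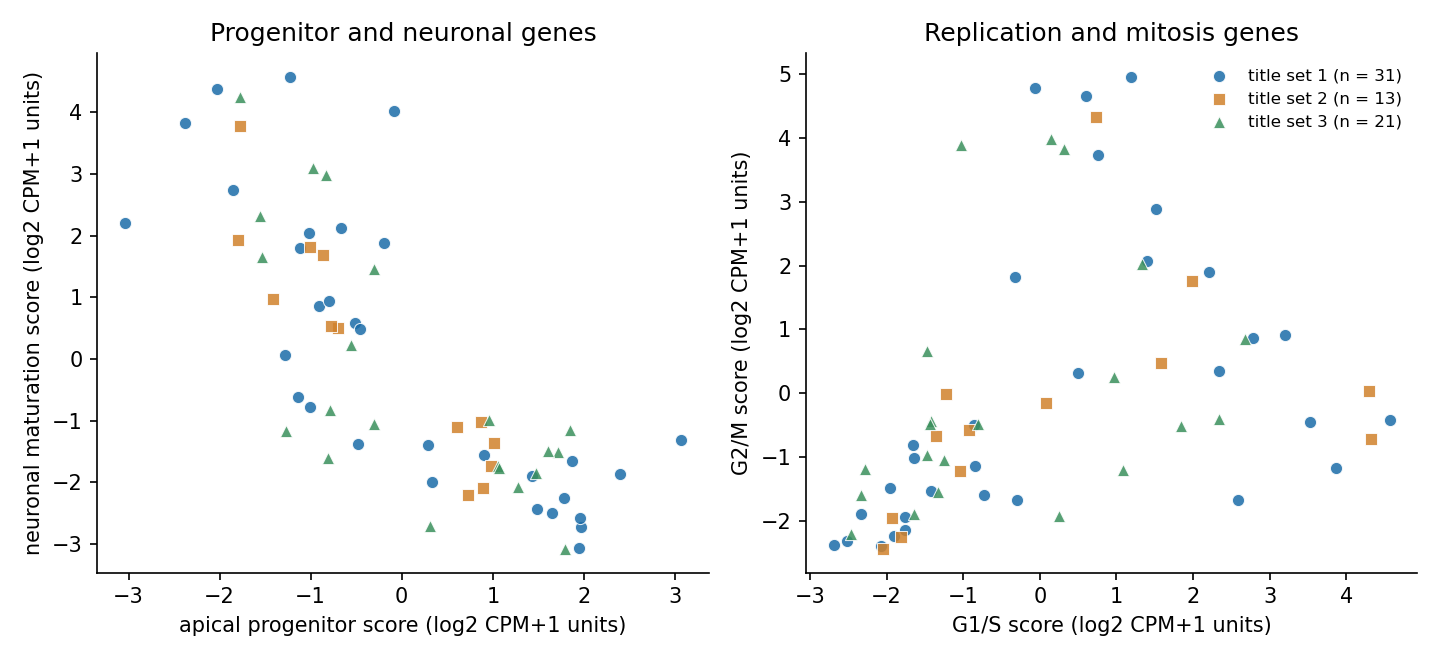
Scores of 65 single cells, 1 point per cell, by title set, in log2(CPM+1) units relative to control genes. In the left panel cells run from high progenitor and low neuronal scores to the reverse (r = -0.787), and in the right panel G2/M scores rise with G1/S scores (r = 0.386).

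A group of cells expressed genes of interneurons and the ventral forebrain, although the ganglionic eminences, where cortical interneurons arise, were removed in dissection. Dlx5 reached 10 CPM in 11 cells, Dlx1 in 9, Dlx2 in 8, the antisense transcript Dlx6as1 in 8, Gad2 in 11 and the transcription factor gene Sp9 in 6. At least 3 of the 12 measured genes of this list reached 10 CPM in 10 of 65 cells (15.4%, 95% interval 7.63 to 26.5), in 6 of 31, 2 of 13 and 2 of 21 cells of sets 1, 2 and 3. A further 2 cells had 2 such genes, 12 had 1 and 41 had none. In the 10 cells Dlx5 had a median of 716 CPM, Dlx1 279, Dlx6as1 227, Dlx2 214 and Gad2 67.2, a contrast with the other 55 cells that follows from how the 10 were chosen.

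The 10 cells had high levels of general neuronal genes, with medians of 934 CPM for Dcx and 3302 CPM for Tubb3, against 2.09 and 867 CPM in the other 55. Neurod6 and Tbr1, genes of excitatory neurons, did not reach 10 CPM in any of the 10, but did so in 16 and 19 of the 55. The 10 cells had a median of 4.5 G2/M genes (1 to 34) and the others 8 (1 to 34). The 10 were not alike. In the 21-cell cluster described below lay 3 of them, with neuronal scores of -1.57, -1.40 and -1.36. In the same order, these 3 had 18, 11 and 21 G1/S genes and 10, 34 and 10 G2/M genes. Neuronal scores of the other 7 ran from -0.620 to 1.45. With at least 1 read in place of 10 CPM, 90.8% of all cells would have 3 or more genes of the list, so that the count rests on a level above single reads.

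**Figure D3:**
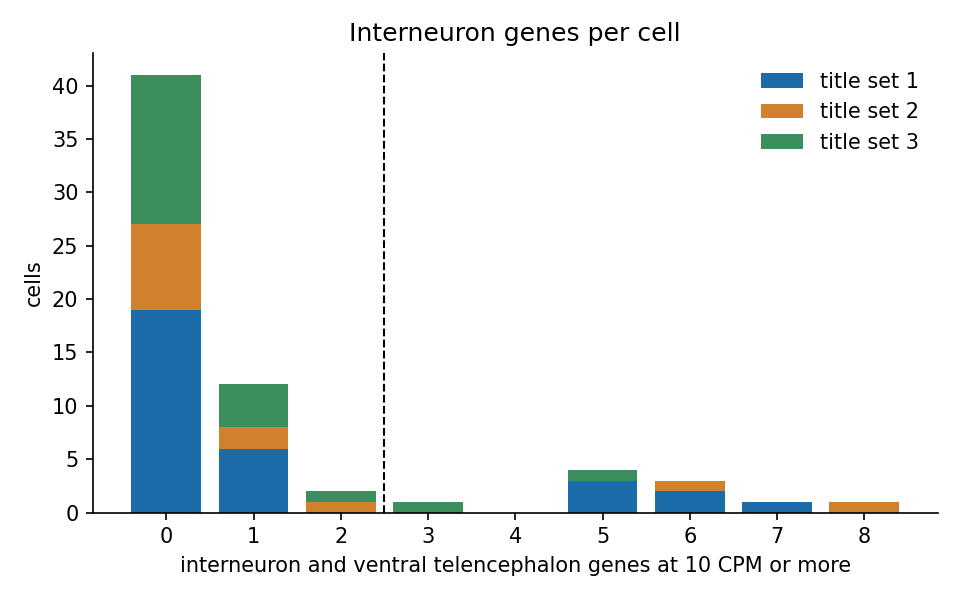
Number of cells by how many of the 12 measured interneuron and ventral telencephalon genes reached 10 CPM, stacked by title set. The dashed line marks the bound of 3 genes, with 10 cells to its right and 41 of 65 cells at 0.

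Red blood cell genes were the most frequent sign of another lineage, and they followed the title sets. Hbb-y, an embryonic globin gene, reached 10 CPM in 44 cells, 10 of 31 in set 1, 13 of 13 in set 2 and 21 of 21 in set 3, with a mean of 373 CPM (SD 618). The globin gene Hba-x was at that level in 4, 13 and 16 cells of these sets and Hbb-bh1 in 1, 13 and 5. Alas2, a haem synthesis enzyme gene of red cells, reached it in 4 cells. Collagen and matrix genes of mural and meningeal cells were confined to few cells, with Col1a2 and Dcn at 10 CPM or more in the same number, 2 cells, and Lum and Col3a1 in 4 each.

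At least 3 genes of another lineage reached 10 CPM in 20 of 65 cells (30.8%, 95% interval 19.9 to 43.4), 1 of 31, 13 of 13 and 6 of 21 in sets 1, 2 and 3. The erythroid list gave 18 of them and the mural and meningeal list 2, both in set 3. No cell had 3 microglia genes, which allows a share of up to 5.52%. Endothelium and oligodendrocyte precursor lists, with 2 and 3 measured genes, had little or no power here. Without the erythroid list, an alternative chosen after seeing the data, the share was 3.08%, and at 50 CPM it was 9.23%.

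Embryos of both sexes can be in the pool, so that Xist, the noncoding RNA of the inactive X chromosome in female cells, and Y-linked genes in the same cell bear on doublets and carried-over RNA. Xist reached 10 CPM in 32 cells and at least 1 of Ddx3y, Eif2s3y, Kdm5d and Uty in 22. The cells were parted by title set, with Xist in 27 of 31, 3 of 13 and 2 of 21 cells and Y-linked genes in 0, 5 and 17 cells of sets 1, 2 and 3. Eif2s3y was the Y-linked gene seen in the most cells, 14. Both kinds were found in 1 of 65 cells, in set 3 (1.54%, 95% interval 0.0389 to 8.28), and neither in 12. Another cell, of set 2, had Xist just under the level (9.87 CPM) with Y-linked genes at 335 CPM. Both were found in 2 cells (3.08%) after thinning or with Rn45s left out of the totals, in 61.5% of cells at 1 read and in none at 50 CPM. In thinned cells 1 read passes 10 CPM. Set 1 had no cell with Y-linked genes and set 3 only 2 with Xist, so that most doublets within these sets would go unseen. Antisense reads of Tsix cannot be told from Xist without strand.

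**Figure D4:**
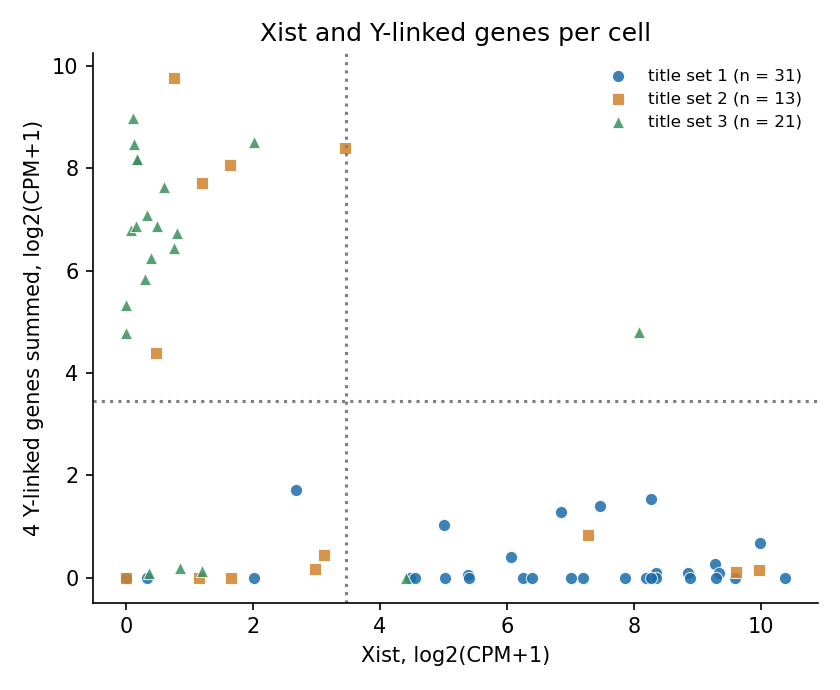
Xist against the sum of 4 Y-linked genes in 65 single cells, both as log2(CPM+1), by title set, with dotted lines at 10 CPM. Of the cells, 1 lies beyond both lines, and 27 of 31 cells of set 1 lie to the right with no Y-linked gene at 10 CPM.

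Clustering without the cell cycle lists gave 6 clusters of 21, 17, 12, 12, 2 and 1 cells, the largest holding 32.3% of cells (95% interval 21.2 to 45.1). The 21-cell cluster, led by the replication genes Rrm2 and Mcm2 with the apical progenitor genes Notch1 and Phgdh behind them, stays unnamed, and had medians of 17 G1/S and 17 G2/M genes per cell. The 17-cell cluster was neuron-like, led by Neurod6, Cnr1, Stmn2, Dcx and Tbr1, with medians of 3 and 4 such genes. A 12-cell cluster led by Stmn2, Dcx and Dlx5 held 7 of the 10 cells with interneuron genes and stays unnamed, because its leading genes belong to more than 1 class. This cluster held 4, 6 and 2 cells of sets 1, 2 and 3, and its cells with fewer than 3 interneuron genes were all of set 2. The other 12-cell cluster, unnamed, held only cells of set 3, and the 21-cell cluster held none of that set. Their median apical progenitor scores were alike (1.07 and 1.02), and their median neuronal scores were -1.50 and -1.74. The 2-cell cluster, of set 3, was mural and meningeal-like, with Lum, Col3a1, Col1a2 and Dcn in the lead, and the single remaining cell, of set 2, stays unnamed.

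The partition was not stable. Mean silhouettes for 2 to 6 clusters were 0.276, 0.312, 0.295, 0.316 and 0.330, and 6 alternatives, among them scran size factors and pseudocount 10, kept 2 clusters with the largest at 96.9%.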

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

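The settings that left out cells under 1000000 reads, Rn45s reads, the cells of the 2 smallest clusters, the cells with interneuron genes, the erythroid list or each list's 2 farthest cells were chosen only after results were seen. Of 145 alternative values whose setting changed something, 116 stayed within the spread set for them and 29 moved. The causes of the moves were not tested. For a score correlation, that spread was the SD of r between the title sets. Counts, shares and the median of detected genes have no sign that could reverse. Only the score correlations could do so, and they kept their sign in every alternative. The number of lists above the 99th percentile ranged from 12, without title set 1, to 16, and the intermediate progenitor correlation from 0.0939 to 0.263, inside its random range. The 23 genes variable in every set became 15 with scran size factors, 12 with no cell replaced and 36 among the 1000 highest. The largest cluster held 96.9% of cells with scran size factors, pseudocount 10, no cell replaced, the detected-gene trend removed, 500 genes or Rn45s left out. It held 46.2% when centred within title sets and 26.9% to 94.1% leaving out 1 title set at a time. Without control genes, the progenitor and neuronal correlation was -0.656, that of G2/M and neuronal scores -0.472 and that of G1/S and G2/M scores 0.502. Spearman's rho for the latter pairs was -0.647 and 0.634. Leaving out title sets gave -0.624 to -0.573 for G2/M and neuronal scores. At 1 read or more, the shares of cells with interneuron genes, genes of other lineages, and both Xist and Y-linked genes were 90.8%, 56.9% and 61.5%. At 50 CPM, the last 2 were 9.23% and 0%. Other lineages reached 53.8% of cells with 2 or more genes, 3.08% without the erythroid list and 13.5% to 55.9% leaving out title sets. Xist with Y-linked genes ranged from 0% to 2.94% leaving out title sets. Thinning to 85338 reads lowered the median of detected genes to 2965, which limits what the shallowest cell can show. The settings without a cell filter or gene filter removed nothing, tested nothing and are not counted here.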

Other observations

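The test for red blood cells caught with sorted cells was written only after the globin values were seen, and the genes of the next paragraph were chosen after their values were seen.

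The 10 cells with interneuron genes differed from the other 55 in further regulators. At 10 CPM or more, Meis2, a homeobox gene of the lateral ganglionic eminence, was found in 9 of the 10 and 20 of the 55, and the transcription factor gene Zfhx3 in 9 and 14. The neurexin gene Nrxn3 was found in 6 and 2, and Isl1, a gene of striatal projection neurons, in 5 and 0. Sp8 was found in 8 and 19, with a median of 864 CPM in the 10. Nfib, a transcription factor gene widely expressed in the cortex, was found in 1 and 47, and Emx1, a gene of the dorsal telencephalon, in 0 and 20. Of 2 medial eminence genes, Nkx2-1 was found in 2 and 1, and Lhx6 in 0 cells of either group.

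In the single cell that clustered alone, Ttr, a thyroid hormone carrier gene of choroid plexus, was at 11115 CPM, against a mean of 1.29 in the other cells. No further cell of this kind was seen, and this gene too was chosen after its value was seen.

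Title sets parted on Xist and Y-linked genes. A difference in depth did not account for this: with every cell thinned to 85338 reads, where 1 read reaches 10 CPM, the share of cells with Xist was still 79.3 percentage points higher in set 1 than in set 3. Loss of long transcripts in set 3 did not either, since 0% of 121 long genes with a similar share in set 1 fell as far as Xist, by 77.6 points. The 2 kinds of genes ran in opposite directions. In set 1, 27 of 31 cells had Xist and 0 had Y-linked genes at 10 CPM. In set 3, 2 of 21 had Xist and 17 had Y-linked genes. These values argue against sets 1 and 3 being drawn from 1 pool with the same mix of sexes. The sex of the embryos behind each set is not given by the labels, so that no biological explanation was tested.

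Erythroid genes were found in every cell of set 2. Embryonic globin also reached 10 CPM in all 21 cells of set 3, with a median of 736 CPM, against 606 CPM in set 2. Embryonic globin reads made up at most 0.561% of the reads of a set 2 cell, but adult globin genes are not analysed here, so that red blood cells caught with sorted cells stay open. Free globin RNA carried over could account for the pattern, since globin CPM differed 4.91 times between the highest and lowest of the 11 set 2 cells above 1000000 reads. Over all 13 set 2 cells the ratio was 28.6, and over the cells of set 3 it was 36.9. In the same 11 set 2 cells, Hbb-y made up 64.6% to 76.5% of the reads of Hbb-y, Hbb-bh1 and Hba-x. In the 21 cells of set 3 this share ran from 1.69% to 99.96%. No biological explanation was tested.

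A cluster of 12 cells held only cells of set 3. A transcript length bias could not be judged: 0 of the 12 shared such a cluster after correction for length, but also 0 without it once the 109 genes of unknown length were left out. Depth was left undecided as well, with 9 of the 12 still together after thinning to 85338 reads. The sets did differ technically. The median slope of log2(CPM+1) on log2 transcript length was -0.174, -0.0541 and -0.333 in sets 1, 2 and 3. Rn45s took 1.43% to 5.55%, 6.61% to 11.05% and 0.0518% to 0.294% of a cell's reads in these sets, without overlap. Whether these differences formed the cluster was not decided. No biological explanation was tested.

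Because the imprinted genes Ndn and Mest were both variable in every title set, imprinted genes were asked to vary together. A list of 32, of which 27 were measured, lay at percentile 99.6 of matched random lists over all cells, led by Meg3, Cdkn1c and Nnat. It lay at 98.8, 63.01 and 99.2 within sets 1, 2 and 3, above the 99th percentile in 1 of the 3, which left the question of the list undecided. Ndn and Mest themselves took no part in its first component (r = -0.00108 and 0.0261) and had an r of -0.0787 with each other, so that this component does not describe the 2 genes that raised the question.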
